A study of Mus musculus with 2 samples.

How the data were processed

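Small RNA libraries of less than 30 nucleotides, per the labels, were made from total RNA of embryonic mouse kidney in 2 biological replicates of 1 group. The authors deposited 1 table of raw read counts per annotated miRNA gene for each library, with no normalization. Per the deposit's file descriptions, reads had been aligned to mm10 and counted on GENCODE release M4; the aligner and the counting program are not given in the sources used here. Each table holds 1973 genes and 3 columns of counts, for both strands, for the strand of the gene and for the opposite strand; the first was the sum of the others in every gene row. Its first 4 rows are tallies that name no gene and were left out of totals and tests.

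Replicate 1 held 10450326 reads and replicate 2 held 6765908, counting the tallies. Unmapped reads were 16.8% and 14.1% of them, reads that mapped to several places 28.3% and 27.5%, and reads on no annotated feature 4.06% and 2.91%. Genes took 5305101 and 3751392 counts on both strands together. Reads that map to several places are in no gene's count, which can lower genes whose mature sequence has a second copy in the genome. Of the 345 detected genes, 66 share a stretch of 21 bases with another annotated miRNA gene. The strand opposite to the genes held 1.93% of assigned counts in replicate 1 (95% exact Clopper-Pearson interval 1.92 to 1.94) and 1.80% in replicate 2 (1.78 to 1.81), a mean of 1.86% ± 0.0957 (SD, n = 2).

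The counts on the strand of the gene were the main measurement. CPM is counts per 1000000 counts assigned to miRNA genes on that strand. A gene was called detected at 10 or more counts in each replicate, and log values used a pseudocount of 1 CPM. Gene symbols, positions and host genes were taken from GENCODE release M21, on the same assembly but later than the authors' release; 1894 of the 1973 identifiers matched without their version, and none of the other 79 had more than 1 count. Host genes are those on the same strand in M21. Shared stretches of 21 bases were found by comparing the hairpin transcripts of that release with one another.

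There was no contrast between groups, so edgeR's quasi-likelihood test was not run. The replicates were compared gene by gene with a two-sided exact binomial test on counts, given totals scaled by TMM factors (1.00 in both libraries), with Benjamini-Hochberg adjustment over the 345 detected genes. A gene was called at an adjusted p below 0.05 and a log2 ratio of at least 1 in size. The test compares the libraries, not conditions, and takes only counting error into account. The common dispersion came from edgeR with an intercept alone. Each list's share was set beside its replicates' SD. Its abundance was ranked among 10000 random lists drawn from the 716 genes with a count, and its median replicate ratio among 10000 random lists matched on deciles of mean abundance. These percentiles are descriptions, not p-values. The replicates were also compared by a chi-square test over genes to see whether they were 1 library given as 2.

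The 24 gene lists, the tests, the alternatives and the rule for named genes were fixed before the data were examined. The rule took the 25 genes of highest mean CPM, up to 4 detected genes per list of highest mean CPM with the undetected members of lists of 10 or fewer, and, among called genes with a mean count of at least 100, the 5 of highest and the 5 of lowest ratio. Only 1 higher and 3 lower genes met the last part. The 6 families compared from highest to lowest member were picked from the lists after the data were examined. Other genes and clusters named in the closing section were chosen after their values were seen.

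Alternatives were other count minimums, DESeq2 size factors or totals alone, an edgeR exact test, other pseudocounts, the DESeq2 dispersion, shares without the most abundant gene, summed counts of lists, members with a mean count of at least 100, the unstranded counts, and each replicate alone. An edgeR exact test with the estimated dispersion and list medians without genes that share sequence were added after the data were examined, as was the hepatocyte share without replicate 2, which repeats a planned setting. The calculations were tested on simulated counts of 341 genes, drawn with counting error alone and no further spread between replicates. At an adjusted p below 0.05 with no minimum of the ratio, the binomial test recovered 16 of 21 genes changed 1.5-fold. It recovered 19 of 24 changed 2-fold, and 26 of 26 at 4-fold and again at 8-fold. Of 244 unchanged genes, 1 passed at any size and 0 at a log2 ratio of 1. These rates check the calculation and do not hold for the real libraries, which differed by more than counting error. In a step on those 244 genes, 1 list moved on purpose reached percentile 100, and 4 of 40 unmoved lists lay outside the middle 95%. Versions were R 4.3.3, edgeR 4.0.16, DESeq2 1.42.0, Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9. Signal tracks and alignments were not used here.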

Results

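MicroRNAs were profiled by small RNA sequencing in kidneys of mouse embryos of the B6NCrl strain at 14.5 days of gestation, a stage at which the ureteric bud is branching and nephrons are forming. There was 1 group, embryonic kidney, with 2 biological replicates. Each replicate was made from 2 kidneys, collected on different days, and libraries covered RNA of less than 30 nucleotides. The labels describe a single pup for each sample and, in other fields, material of both sexes and 1 donor identifier shared by both samples. If the 2 replicates were collected on different days, they came from different embryos. The labels do not settle how many embryos each sample holds. Each SD and coefficient of variation measures only the spread between these 2 samples, which may be partly technical. The p-values concern these 2 libraries or genes within them, and none measures the spread between animals. Replicate 1 had 5202588 counts on the strand of annotated miRNA genes, and replicate 2 had 3683978. With these totals, 3 counts correspond to 0.577 CPM (counts per 1000000 counts assigned to miRNA genes) in replicate 1 and 0.814 CPM in replicate 2. All intervals given here cover counting error only and treat reads as independent. PCR reads without molecular identifiers are not independent molecules, so the intervals may be too narrow. The design has no contrast between conditions, and the comparisons are between miRNA genes, between lists of miRNA genes and between the replicates.

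Among counts assigned to genes on their own strand, a small number of miRNA genes dominated, led by miRNAs encoded inside the Hox clusters. Reads that mapped to several places, 28.3% of reads in replicate 1 and 27.5% in replicate 2, are in no gene's count. Ranks and shares leave these reads out, as well as counts on the opposite strand. On that strand Gm25301 had a mean of 7796 CPM, more than Mir130b, the gene of rank 25, at 7519 CPM. Mir10a was the most abundant gene at 144007 ± 2037 CPM (SD, n = 2), followed by Mir335 at 92131 ± 12421 CPM, Mir10b at 71380 ± 1240 CPM and Mir126a at 46469 ± 1824 CPM. The 10 most abundant genes, which also included Mirlet7i, Mir99a, Mirlet7g, Mir17, Mir322 and Mir196b, held 55.6% ± 1.20 of counts (SD, n = 2). In replicate 1 their share was 54.7% (95% exact binomial interval 54.7 to 54.8), and in replicate 2 it was 56.4% (56.4 to 56.5). The 25 most abundant genes held 77.5% of counts in replicate 1 and 78.2% in replicate 2. Of the 1973 annotated miRNA genes, 345 had at least 10 counts in each replicate and are called detected, and 1257 had no count in either.

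**Figure D1:**
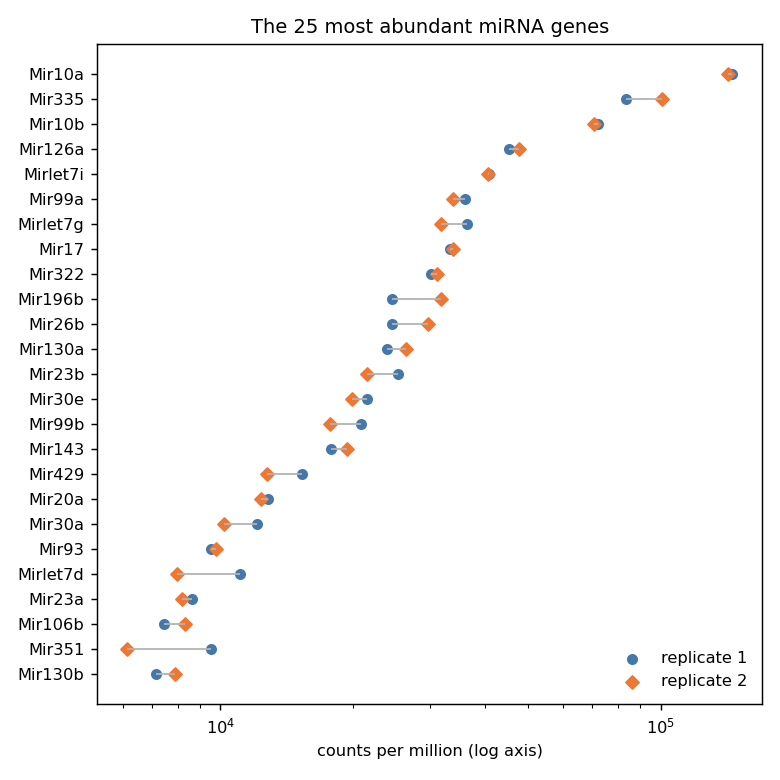
Abundance of the 25 miRNA genes with the highest mean, in CPM on a log axis, with 1 point per replicate and a grey line joining the 2 replicates of a gene. Mir10a lies highest at a mean of 144007 CPM, and the widest gap between replicates is that of Mir351.

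The 6 miRNA genes of the Hox clusters, genes that pattern the body axis, held 25.2% ± 0.157 of counts (SD, n = 2), and all 6 were detected. Mir10a (ENSMUSG00000065519.1; mm10 chromosome 11, 96317165 to 96317274) lies near the Hoxb genes with no annotated host on its strand. Mir10b (chromosome 2, 74726070 to 74726137) lies in introns of Hoxd3 and Hoxd4 transcripts. Mir196b, in an exon of a Hoxa9 transcript (chromosome 6, 52230081 to 52230165), reached 28115 ± 4986 CPM, and Mir615, in an intron of Hoxc5, reached 5916 ± 268 CPM. The median of this list lay above that of every one of 10000 random lists of the same size. Some lists described below ranked nearly as high, with percentiles of 99.99 for Dlk1-Dio3, 99.95 for let-7 and 99.86 for miR-200. Others did not, such as the kidney tubule list at 22.3. With Mir10a taken out of both the list and the total, the remaining genes held 12.6%. Mir335, the gene of second-highest abundance, lies in an intron of the imprinted gene Mest (chromosome 6, 30741299 to 30741396).

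The let-7 family, which rises as tissues differentiate, held 9.35% ± 0.648 of counts, with 10 of 10 counted genes detected. Mirlet7e and Mirlet7f-1 have no row of counts, so the family's share may be understated. The leading counted genes of the family were Mirlet7i at 40642 ± 108 CPM, Mirlet7g at 34042 ± 3298 CPM, Mirlet7d at 9549 ± 2198 CPM and Mir98 at 5868 ± 279 CPM. The miR-17 cluster and its paralogous clusters, associated with proliferation of progenitor cells, held 7.52% ± 0.0388, with 15 of 15 genes detected. Mir17 reached 33519 ± 256 CPM and Mir20a 12589 ± 313 CPM, and Mir93 and Mir106b of the paralogous cluster in Mcm7 reached 9659 ± 207 and 7886 ± 629 CPM. The miR-30 family held 3.59% ± 0.267, led by Mir30e at 20748 ± 1188 CPM and Mir30a at 11164 ± 1377 CPM, with Mir30d at 3650 ± 148 CPM and Mir30c-1 at 120 ± 22.3 CPM. Reads that mapped to several places were tallied apart from genes, so counts of members that share their sequence with another gene (among them let-7a, let-7c, let-7f, miR-30c, miR-19b and miR-92) are uncertain.

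Lists for the cell types of the kidney differed widely in share. Mir126a, which lies in Egfl7 and is abundant in endothelial cells, held 4.65% ± 0.182 of counts. The mesenchymal, stromal and smooth muscle list held 3.58% ± 0.00770, with 9 of 10 genes detected, led by Mir143 at 18645 ± 1069 CPM, Mir21a at 7260 ± 543 CPM, Mir214 at 6006 ± 667 CPM and Mir22 at 3045 ± 167 CPM. The miR-200 family of epithelial cells held 2.51% ± 0.234, with 5 of 5 genes detected, led by Mir429 at 14037 ± 1789 CPM, Mir200c at 5062 ± 308 CPM, Mir200b at 4619 ± 226 CPM and Mir141 at 719 ± 26.1 CPM. The list of miRNAs described in kidney tubules held 0.0425% ± 0.00983, and 3 of its 9 genes were detected: Mir192 at 174 ± 70.1 CPM, Mir204 at 146 ± 14.8 CPM and Mir194-2 at 100.3 ± 41.3 CPM. Mir194-1, Mir211, Mir215, Mir216a, Mir216b and Mir217 did not reach the minimum, and Mir194-2 and Mir194-1 share sequence, so their counts are uncertain. Hypoxia-responsive Mir210 was at 287 ± 20.1 CPM.

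Among imprinted loci, the Dlk1-Dio3 cluster held 1.68% ± 0.149 of counts, with 40 of 46 genes detected. Its leading genes were Mir411 at 2843 ± 417 CPM, Mir127 at 1734 ± 49.4 CPM, Mir487b at 1616 ± 159 CPM and Mir431 at 1515 ± 176 CPM. The H19-Igf2 locus held 0.195% ± 0.0429, with Mir483, in an Igf2 intron, at 1872 ± 426 CPM and Mir675, in H19, at 82.0 ± 3.43 CPM. The repetitive cluster in Sfmbt2 held 0.552% ± 0.0321, with 10 of 69 genes detected. Mir467d, Mir467e, Mir467c and Mir669l were its leading genes, at 1786 ± 264, 1500.0 ± 9.68, 1107 ± 74.1 and 468 ± 9.73 CPM, and all 10 detected genes share a stretch of 21 bases with another miRNA gene, so their counts are uncertain.

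Lists for other cell types held small shares. The miR-183 cluster of sensory epithelia held 0.843% ± 0.0391, with Mir182 at 4792 ± 211 CPM, Mir183 at 2492 ± 171 CPM and Mir96 at 1146 ± 9.06 CPM. Mir203 and Mir205 of stratified epithelium held 0.232% ± 0.0127, at 1650 ± 74.3 and 668 ± 52.5 CPM. The endocrine list held 0.0879% ± 0.000783, with most of its counts in Mir375 at 789 ± 6.95 CPM. Mir7-1 was at 77.8 ± 2.53 CPM, Mir7-2 at 6.93 ± 0.561 CPM and Mir7b at 4.51 ± 2.84 CPM. Mir7-1 and Mir7-2 share a stretch of 21 bases with another gene, so their counts are uncertain and the part of Mir375 may be overstated. The multiciliated list held 0.0767% ± 0.00285, led by Mir34c at 619 ± 20.96 CPM and followed by Mir34a, Mir34b and Mir449a. The leukocyte list held 0.0735% ± 0.0000968, with Mir155 at 336 ± 36.0 CPM, Mir223 at 267 ± 1.86 CPM, Mir146 at 119 ± 33.8 CPM and Mir150 at 13.0 ± 0.357 CPM, while Mir142b and Mir146b were below the minimum on their own strand. Mir142b had 318 ± 7.96 CPM on the opposite strand, and the list's share was 0.103% with unstranded counts. The neural list held 0.0684% ± 0.00769, led by Mir132 at 399 ± 61.2 CPM, Mir128-1, Mir212 and Mir138-2, with 9 of 14 genes detected. The 5 that were not, Mir9-2, Mir9-3, Mir124a-1, Mir124a-2 and Mir124a-3, share sequence with other genes, so their low counts are uncertain. So are the counts of 6 of the 9 detected neural genes, among them Mir128-1 and Mir138-2, and of Mir146 in the leukocyte list, which also share sequence.

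A further group of lists held still smaller shares or differed between replicates. The erythroid list held 0.0119% ± 0.00590, with 0.0161% in replicate 1 and 0.00776% in replicate 2. It was made up of Mir451a at 81.9 ± 46.4 CPM, Mir144 at 31.4 ± 10.6 CPM and Mir486 at 6.06 ± 2.04 CPM. Skeletal and cardiac muscle miRNAs held 0.00746% ± 0.00152, in which Mir206 at 62.9 ± 13.3 CPM and Mir499 at 3.25 ± 0.784 CPM were detected, and Mir1a-1, Mir1b, Mir133a-1, Mir133a-2, Mir133b, Mir208a and Mir208b were not. The miR-1 and miR-133 genes share sequence with one another or with other genes, so their low counts are uncertain. Of the miR-302 cluster of the early embryo, at 0.00301% ± 0.000663, Mir302a, Mir302d and Mir302b were detected, and Mir302c and Mir367 were not. None of the 7 genes of the pluripotency cluster Mir290a, Mir291a, Mir291b, Mir292, Mir293, Mir294 and Mir295 was detected, at 0.000500% ± 0.0000543 together. Mir202 of the gonad had 0 counts, which allows up to 0.577 CPM in replicate 1 and 0.814 CPM in replicate 2. Mir122, the main miRNA of hepatocytes, stood at 56.3 CPM in replicate 1 and 1074 CPM in replicate 2.

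**Figure D2:**
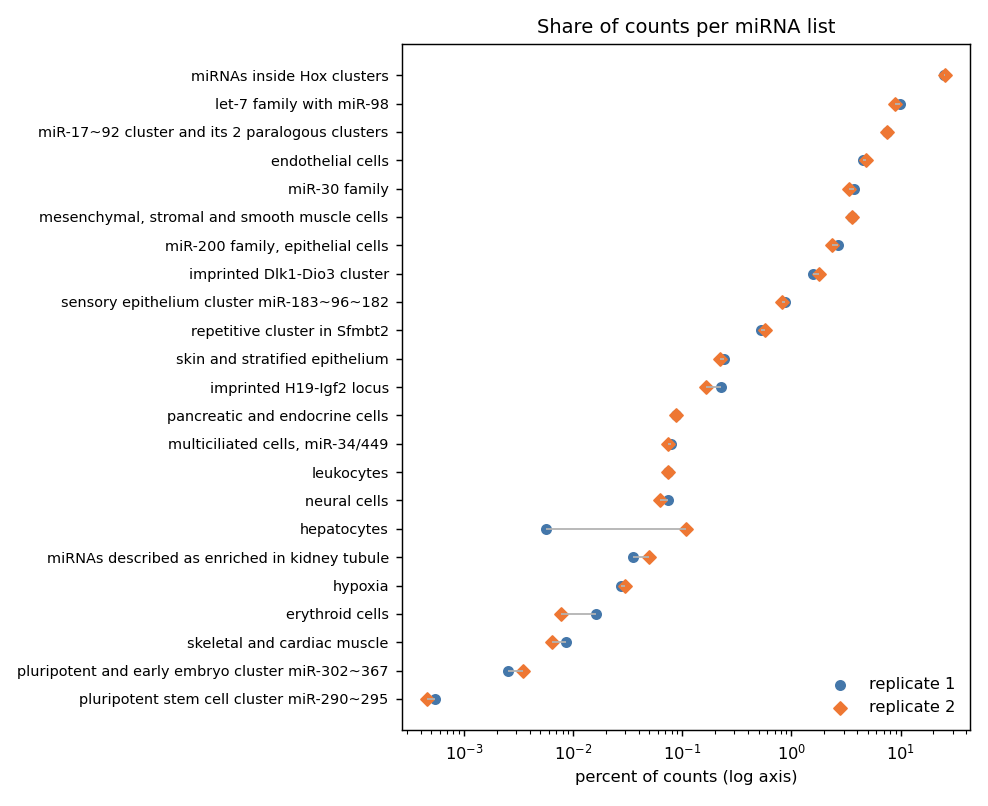
Percent of counts held by each list of miRNA genes, on a log axis, with 1 point per replicate. The Hox cluster miRNAs held the highest share at 25.2%, and the hepatocyte list, which is Mir122 alone, has the widest gap between replicates. Mir202 of the gonad, with 0 counts, is not drawn.

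In each of 6 sets compared, the highest and lowest members of one cluster or family were set against each other. Both were picked by abundance in these same counts, so a positive difference was fixed in advance and its size is only described. These are differences in read counts, and an error alike in both libraries would not appear in the SD. In the miR-17 cluster, transcribed as one RNA, Mir17 exceeded Mir19b-1 by 9.64 ± 0.18 on the log2 scale (SD, n = 2). In the miR-200 family Mir429 exceeded Mir200a by 4.31 ± 0.09, in the miR-106b cluster Mir93 exceeded Mir25 by 3.20 ± 0.27, and in the miR-183 cluster Mir182 exceeded Mir96 by 2.06 ± 0.05. In the let-7 family Mirlet7i exceeded Mirlet7c-2 by 9.15 ± 0.37, and in the miR-30 family Mir30e exceeded Mir30c-2 by 8.10 ± 0.20. The lowest members of the let-7, miR-30 and miR-17 sets share a stretch of 21 bases with another gene, so these 3 differences are uncertain. Members that share no such stretch were also low, with Mir19a at 58.6 ± 1.92 CPM and Mir30b at 117 ± 20.2 CPM. Only annotated hairpins were compared, so reads of these 2 genes may still map to several places.

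The replicates had closely similar profiles. Across the 345 detected genes, which are not independent replicates, Pearson's r of log2(CPM + 1) was 0.992 and Spearman's rho was 0.990. The median absolute log2 ratio was 0.24, and 291 genes (84.3%) differed by less than 1.5-fold. Of the 25 most abundant genes, 24 did, the exception being Mir351 with a log2 ratio of replicate 2 over replicate 1 of -0.63. The common biological coefficient of variation was 0.199 in edgeR, and the DESeq2 median dispersion gave 0.0771. The counts differed by more than sampling noise (chi-square 46611 on 344 degrees of freedom), so they were not treated as 1 library given as 2. That test does not show that they came from separate animals.

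Mir122 differed most between the replicates. It had 293 counts in replicate 1 and 3957 in replicate 2, a log2 ratio of 4.26 (95% exact interval 4.09 to 4.43). In the exact binomial test, 11 genes differed at an adjusted p below 0.05 and a log2 ratio of at least 1 in size, 3 higher and 8 lower in replicate 2. Of the 4 with a mean count of at least 100, Mir122 (chromosome 18, 65248861 to 65248926) was higher, and Mir6236 (log2 ratio -1.69, 469 and 103 counts), Gm23935 (-1.38, 368 and 100 counts) and Mir451a (-1.22, 597 and 181 counts) were lower in replicate 2. Gm23935 shares a stretch of 21 bases with 5 other miRNA genes, so its counts are uncertain. This test compares the libraries, with counting error only. With an assumed coefficient of variation of 0.2 in place of counting error alone, edgeR's exact test of 1 library against the other called 2 genes, Mir122 (adjusted p 9.36e-17) and Mir6236 (adjusted p 0.0308), while Mir451a (adjusted p 0.42) and Gm23935 (adjusted p 0.248) did not pass. With 1 library on each side, these values depend on the assumed spread and do not show a difference beyond that between replicates.

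**Figure D3:**
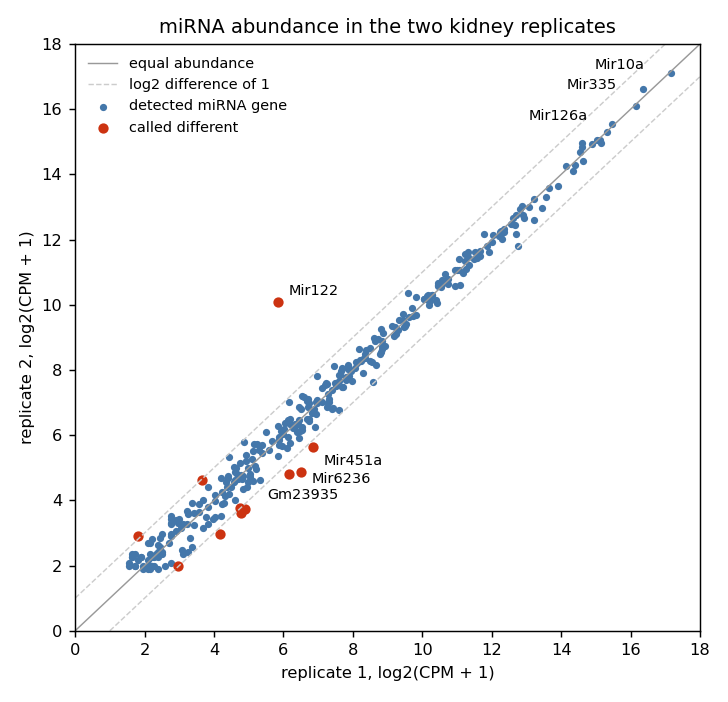
Abundance of the 345 detected miRNA genes in replicate 1 and replicate 2, as log2(CPM + 1), with 1 point per gene. The solid line marks equal abundance, dashed lines a log2 difference of 1, and red points the 11 genes called different by the exact binomial test. Mir122 lies farthest from the line, at a log2 ratio of 4.26.

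The let-7 list had lower and the Dlk1-Dio3 list higher counts in replicate 2. Without members that share sequence, both medians came to lie inside the middle 95% of random lists, the Dlk1-Dio3 median narrowly. Of 16 lists with at least 3 detected genes, 4 had a median log2 ratio outside the middle 95% of random lists matched on abundance, against 0.8 expected for independent genes. Ratios of genes in the same genomic cluster were correlated (intraclass correlation 0.430), and all 4 lists hold such neighbours, so 0.8 understates the number expected by chance. In data simulated with counting error alone, 4 of 40 lists with no change (10%) also fell outside. The percentiles describe these libraries, and 186 of all 345 detected genes (53.9%) passed at an adjusted p below 0.05 with no minimum of the ratio.

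The let-7 list had a median of -0.34 (percentile 0.08). Of its 10 genes, 9 passed as lower, and 9 adjusted over the list alone, among them Mirlet7d at -0.47 and Mirlet7g at -0.19, and Mirlet7i, at -0.0018, did not. Its summed counts had a log2 ratio of -0.14. For the 5 members that share no stretch of 21 bases with another gene, the median was -0.19 (percentile 10.6), inside the middle 95%. All 5 were lower in replicate 2. The middle 95% of random lists was wider at that size, -0.25 to 0.14 against -0.21 to 0.15 for 10 genes. The restriction to such members was added after the data were examined. The Dlk1-Dio3 list had a median of 0.18 (percentile 99.5), and 19 of its 40 detected genes passed as higher and 3 as lower, the same numbers as adjusted over the list alone, with Mir411 at 0.30 and Mir431 at 0.24. Its 37 members without a shared stretch had a median of 0.1545 (percentile 97.1), just inside the upper limit of 0.1568, with 28 higher and 9 lower. In the kidney tubule list (median 0.85, percentile 99.9), Mir192 at 0.85 and Mir194-2 at 0.87 were higher and Mir204 at -0.20 was lower in replicate 2, and 3 of 3 passed, also adjusted over the list alone. The erythroid list (median -0.70, percentile 1.60) had Mir451a and Mir144 lower in replicate 2, also adjusted over the list alone, and Mir486 at -0.70 did not pass. Mir122 was higher in the same replicate in which Mir192 and Mir194-2 were higher and Mir451a and Mir144 lower.

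The remaining 12 lists lay within the middle 95% of random lists, which does not show that they were unchanged. The miR-200 family had a median of -0.12 and a log2 ratio of summed counts of -0.19, and 4 of its 5 genes passed as lower, with 1 more as higher when adjusted over the list alone. In the miR-30 family the median was 0.04 and the summed ratio -0.15, with 2 of 6 genes passing as higher and 3 as lower. Of the 15 miR-17 cluster genes, at a median of 0.04, 5 passed as higher and 5 as lower. Of the 6 Hox miRNAs, at -0.02, 2 passed as higher and 3 as lower. Of 9 mesenchymal genes, at -0.06, 4 passed as higher and 2 as lower. Of 9 neural genes, at -0.03, 1 passed as higher and 3 as lower, and of 10 Sfmbt2 genes, at 0.08, 3 as higher and 1 as lower. The leukocyte list, at -0.02, had 1 of 4 in each direction, the miR-183 cluster, at -0.09, had 2 of 3 lower, and the endocrine list, at 0.10, had 1 of 4 higher. No gene of the miR-302 cluster, at 0.50, or of the multiciliated list, at -0.12, passed. Apart from the miR-200 family, these counts were the same adjusted over the list alone. The summed ratio had the opposite sign to the median for the miR-30, Hox, mesenchymal and leukocyte lists.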

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

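All tests in this part were chosen after the counts they bear on had been seen. The design has 1 group, and no biological explanation was tested.

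Counts on the strand opposite to the genes, which are outside the report's main measurement, exceeded 3 in both replicates for 14 genes. The mean counts there were 34714.5 for Gm25301, 20195.5 for Gm25927, 11697 for Gm24083, 6237.5 for Gm24321, 3076 for Gm25252, 2749 for Mir497b, 2684 for Mir299b, 1417.5 for Mir142b, 1309.5 for Gm25750, 411 for Gm24111 and 343.5 for Mir3074-1. They were 24.5 for Mir126a, 23 for Mir203 and 12 for Mir708, whose counts lie almost wholly on their own strand.

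The first 11 of these genes had most of their counts on the opposite strand and held 99.8% of all opposite-strand counts. A loss of strand in the library would put a like share in every abundant gene, but the median share of opposite-strand counts over the 100 most abundant genes was 0%, with a highest value of 0.311%. A candidate explanation is a gene annotated opposite to the miRNA: in GENCODE M21, 11 of 11 overlap a miRNA gene on the other strand that has no row in the count tables, against 18 of 710 other genes (Fisher's exact p = 5.45e-17). The partners are Mir378a, Mirlet7e, Mir191, Mir409, Mir376a, Mir497, Mir299a, Mir142, Mir380, Mirlet7f-1 and Mir24-1, so these miRNAs may be missing from the report's counts and from its let-7, leukocyte and Dlk1-Dio3 lists. Replicate ratios (log2) were -0.26 and -0.46 for the let-7e and let-7f-1 partners, and -0.12, 0.12, 0.11 and -0.0026 for those of Mir409, Mir376a, Mir299a and Mir380. The ratio for that of Mir142 was -0.05, at 318 ± 7.96 CPM, and with unstranded counts the leukocyte share was 0.103%.

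Reads that mapped to several places made up 27.9% ± 0.566 of reads (SD, n = 2) and are in no gene's count. In 9 families, the 24 members that share a stretch of 21 bases with another miRNA gene had a median of 138 CPM, and the 21 members that do not had 4334 CPM. Within families the mean difference was -3.78 on the log2 scale (permutation p = 2e-05), so low counts of let-7a, let-7c, miR-30c and similar genes may reflect reads left out because they map to several places. With families defined by the number in the symbol, the difference was -3.08 over 14 families (permutation p = 2e-05), and -3.45 without the Sfmbt2 prefixes (permutation p = 3e-05). Single members went the other way: Mir92-1, which shares such a stretch, was at 4578 CPM against 1059 CPM for Mir25 and 214 CPM for Mir363, which share none, Mir16-1 (2167 CPM) exceeded Mir195a (556 CPM), and Mir29c (67.5 CPM) exceeded Mir29a (41.1 CPM). How much of the difference is transcription stays open, since reads of identical mature sequences cannot be assigned.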

How the results depend on the processing

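The edgeR exact test with an estimated dispersion was chosen after the data were examined, and the hepatocyte share without replicate 2, named again then, had already been planned. List medians over members that share no stretch of 21 bases were also added then; the let-7 (-0.19) and Dlk1-Dio3 (0.15) medians came to lie inside the middle 95% of random lists, and 2 tubule genes were too few. With no filter on low counts, 577 miRNA genes had a count in each replicate. The number of genes that differ between replicates was 2 in the edgeR exact test with an assumed coefficient of variation, 2 with the estimated dispersion, and 186 with no minimum of the log2 ratio, which by construction admits small ratios. The DESeq2 median dispersion gave a coefficient of variation of 0.0771. It is a median over estimates for single genes, whereas edgeR fits a common dispersion over all genes, so these are different measures. Without the most abundant gene in the total, shares were 10.9% for the let-7 family and 8.78% for the miR-17 clusters, by construction of the smaller total. The share of the Hox miRNAs was 12.6%, since Mir10a leaves that list as well. With unstranded counts they were 7.38% for the miR-17 clusters and 24.7% for the Hox miRNAs, whose totals include the opposite strand. Part of the settings could not have moved a value past the limit and say nothing about stability. With 2 replicates a mean without 1 of them shifts by less than 1 SD (22 main values and 42 for single lists). Scaling, and unstranded counts in the case of single genes, shift log2 ratios by about 1 constant (128 together). Single replicates moved the hepatocyte share from 0.0565% to 0.107% or 0.00563%, and the erythroid share from 0.0119% to 0.00776% without replicate 1. Of the values left, 25 main values and 82 for single genes or lists stayed within the SD or 1.5 times the count, and 18 of the latter moved, among them the leukocyte share, at 0.103% with unstranded counts. Some that stayed could not have moved either. An example is the miR-200 median over members that share no stretch, since no member of that family shares one. These numbers therefore overstate stability. No paired analysis was possible because there is 1 group. Depth limits genes near 10 counts: 42 genes reached 10 counts in 1 replicate only.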

Other observations

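Of the tests in this part, those on miR-122 were chosen after its counts had been seen. The test of genomic clusters was chosen before its result was seen, and its repeats on subsets were added after.

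Several genomic clusters were abundant that the report does not describe as clusters; Mir143, Mir145a and Mirlet7c-1 among their members are also in its lists. The X-linked cluster of Mir322, Mir351, Mir503, Mir542, Mir450b, Mir450-1 and Mir450-2 (mm10 chromosome X, 53047997 to 53054349) held 4.04% ± 0.166 of counts (SD, n = 2), most of it in Mir322 at 30535 ± 675 CPM. Within it, Mir351 had a log2 ratio of replicate 2 over replicate 1 of -0.63 and Mir450b one of 0.65, so members of 1 cluster also went opposite ways. Mir99a and Mirlet7c-1 on chromosome 16 held 3.49% ± 0.152, Mir23b and Mir27b on chromosome 13 held 2.59% ± 0.223, Mir99b and Mir125a on chromosome 17 held 2.33% ± 0.239, and Mir143 and Mir145a on chromosome 18 held 1.90% ± 0.110. In the last pair, Mir143 stood at 18645 ± 1069 CPM and Mir145a, a marker of smooth muscle like its neighbour, at 383 ± 35.8 CPM.

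Mir122, the leading miRNA of hepatocytes, had 293 counts in replicate 1 and 3957 in replicate 2, a log2 ratio of 4.26. For reads shared with a near-identical copy, Mir122 shares a stretch of 21 bases with 0 other miRNA genes. Only annotated hairpins were compared, and reads that map to several places are in no gene's count. This check therefore cannot decide whether a copy bears on the difference between replicates. RNA or reads from a liver sample may be the source: 7 of 7 detected genes of a liver-abundant list had higher values in replicate 2 (median log2 ratio 0.32, percentile 96.955 of matched random lists). That list was written after Mir192, Mir194-2 and Mir29a had been seen to be higher, 2 of its genes are also in the tubule list, kidney expresses its members, and undetected Mir802 had 21 and 7 counts, so the test leaves this open. Fetal liver tissue with blood-forming cells would add erythroid miRNAs, whose summed counts had a log2 ratio of -1.05 (95% exact interval -1.25 to -0.85), with Mir451a at 49.1 CPM in replicate 2, but blood content can differ between samples for other reasons, and liver tissue cannot be told apart from other sources here.

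A hypothesis tested on the same libraries is that members of a genomic cluster differ between replicates together. Over 130 genes in 39 clusters (neighbours within 10 kb on 1 strand, mean count of at least 100), the intraclass correlation of log2 ratios was 0.430, against -0.163 to 0.181 in the middle 95% of permuted cluster labels (permutation p = 1e-05, the smallest that 100000 permutations can give). Leaving out any 1 cluster gave 0.358 to 0.486. It was 0.444 without the Dlk1-Dio3 list and 0.344 without genes that share a stretch of 21 bases. This is consistent with replicate differences that act on whole primary transcripts, in 2 libraries only, and cell composition and dissection were not tested.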
